A study of Mus musculus with 3 samples.

How the data were processed

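Livers of CD-1 mice were flash frozen, RNA was extracted with Trizol, and libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols. The labels give 3 groups of 1 library each. They do not state the sex or age of the animals, how many animals went into a library, when the control was taken or at what hour livers were collected.

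The deposited values are estimated counts per gene, not normalized, per the file headers and the values themselves. Of the values above 0, 70.4% in the control, 70.2% at 8 weeks and 71.5% at 12 weeks were whole within 0.005, and the others carried fractions. The submitters' processing notes name TopHat2 2.1.0 and Cufflinks 2.2.1.0, and the builds mm9 and mm10 without a role. The counting program and its use of strand were not given in the sources used here, so a read in overlapping genes on opposite strands may be counted for either. The files list 49492 entries with positions. Of their symbols, 95.4% were found in GENCODE release M21 (GRCm38), and 90.9% of those had the same start and end, so the coordinates are those of mm10. Spreadsheet dates stood in place of 26 symbols, and 23 were restored by position.

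Estimated counts were rounded to whole numbers. Library sizes were scaled by the TMM method in edgeR 4.0.16 (R 4.3.3), with factors of 0.997, 1.005 and 0.999 for the control, 8-week and 12-week libraries. The design fixed before the data were examined assumed FPKM-like values and stated that CPM after TMM would replace them if the files held counts, which was done. A gene was kept at 1 CPM or more in at least 1 of the 3 libraries, and 1 CPM was added before taking log2 ratios, which understates the change of low genes. Genes were called at 2-fold, a rule of size and not a test. Exact (Clopper-Pearson) 95% intervals of the ratio of counts, without the added CPM, cover counting error only. For a gene at 0 counts in 1 library, the fold is a lower bound against 3 counts there.

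For 44 gene lists fixed in advance (pathways, sex-biased genes and markers of cell types), the median log2 ratio was set among 10000 random lists of the same size matched on mean expression in 20 bins. The 41 lists with at least 5 kept genes have such a position, which describes these libraries and is no test. Outside the central 95% lay 24 lists at 8 weeks, 21 at 12 weeks and 24 between the treated libraries. About 2.05 would lie there if the lists held unrelated genes drawn at random. Genes of a list may vary together between animals, and some lists share genes, so 2.05 is no chance value for these libraries. Adipocyte, pancreatic and intestinal markers had 3, 4 and 2 kept genes.

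Named genes followed a rule fixed in advance. It took the 10 highest and 10 lowest genes against the control with at least 5 CPM in 1 of the 2 libraries (5 and 5 between treated libraries), up to 4 called members of each list or else its 2 most abundant, and 18 genes tied to the study's subject. Predicted and short genes were passed over, and not every gene the rule takes is printed. Genes outside the rule, among them single called members of a list, were chosen after their values were seen.

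The calls and intervals were tested on counts simulated with counting noise only, for 14356 genes. For 8 weeks against control, 94.0% of genes simulated at 3-fold higher were called, 84.0% of those lowered to a matching degree, and 2.04% of those at 1.5-fold, with 0 unchanged genes called there, 3 for 12 weeks against control and 1 between the treated libraries. With noise taken from the difference between the treated libraries, a mean of 340 and 339 unchanged genes were called for 8 and 12 weeks against control, where 912 and 650 were called in the data. List positions were tested on the same counts with normal noise added to the log2 ratios. Of 100 lists left unshifted, 4 lay outside the central 95%. Those lists were drawn at random, so this does not cover lists of genes that vary together. Amplified reads without molecular identifiers are not independent molecules, which the intervals do not cover. Alternatives were other pseudocounts, filters, thresholds and scalings, including DESeq2 1.42.0 size factors. Statistics were computed with Python, numpy, pandas and scipy.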

Results

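Gene expression was measured by RNA sequencing of total RNA from the livers of CD-1 mice, an outbred laboratory strain. Mice received a sonicated suspension of zinc oxide (ZnO) nanoparticles by mouth at 25 mg/kg body weight per day for 8 or 12 weeks, and control mice received phosphate-buffered saline. The series holds 3 libraries, 1 per group, so no difference has a replicate check and no p-value is given. The deposited counts summed to 13614979 in the control, 14258770 in the 8-week library and 13263211 in the 12-week library. At this depth, 3 counts corresponded to 0.221, 0.209 and 0.227 CPM (counts scaled to library size) in the same order. The study's title concerns insulin resistance induced by the particles. Each change below is the log2 ratio of CPM + 1 between 2 libraries over 14585 genes, and a gene was called higher or lower at 2-fold. Intervals are exact 95% intervals of the count ratio and cover counting error only.

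The first comparison asked how the liver after 8 weeks of ZnO nanoparticles differed from the control. At 2-fold, 16 of 18 macrophage markers and 12 of 21 female-biased liver genes were higher, and 11 of 23 male-biased genes and 7 of 45 genes of fatty acid oxidation were lower. Of 36 lipogenic genes, 12 were higher and 5 lower. Scd1, the desaturase that makes monounsaturated fatty acids, went from 826 to 15140 CPM (log2 ratio 4.19). Cyp2b9, a cytochrome P450 found mainly in female liver, went from 1.03 to 255 CPM (6.98). Elovl3, a fatty acid elongase found mainly in male liver, went from 115 to 2.79 CPM (-4.93). In all, 605 genes were at least 2-fold higher and 307 at least 2-fold lower, of which 505 and 234 were protein-coding. Leaving out the 39 genes found in the 8-week library alone, a choice made after seeing the data, left 566 higher and 307 lower.

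Of 21 female-biased liver genes, 12 were higher and 1 was lower, Ntrk2 (-1.35, chosen after its values were seen), with a median log2 ratio of 1.56 that did not move when the 2 genes without control counts were set to their bound. Cyp2a4 (5.46), Cyp2b13 (3.89) and the transporter Slc22a26 (3.20) followed Cyp2b9. Of 23 male-biased liver genes, 11 were lower and 0 higher, with a median of -0.94. Mup21 (-4.34), Mup20 (-3.07) and Mup7 (-2.39) encode major urinary proteins, which carry pheromones. The Mup genes and pseudogenes together made up 1.62% of control counts and 0.747% at 8 weeks. The P450 and Mup families hold near-identical copies, and values of single members are uncertain. Y-linked Ddx3y had a log2 ratio of -0.08 and Eif2s3y of -0.15, and X-linked Xist, chosen after its values were seen, had 14 counts in the control and 9 at 8 weeks. Of 41 cytochromes P450 of families 1 to 3, 14 were higher and 2 lower (median 0.52), with Cyp2a5 at 2.57.

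Of 36 genes of fatty acid and triglyceride synthesis, 12 were higher and 5 lower, with a median of 0.55. In the same library 8 of 21 clock genes were higher and 4 lower. Thrsp, a regulator of lipogenesis, had a log2 ratio of 4.72 and the elongase Elovl6 of 2.83. Cholesterol synthesis and uptake had 12 higher and 0 lower members among 27 (median 0.92). These included Fdps (1.78), Aacs (1.88) and the phosphatidate phosphatase Lpin1, which went from 186 to 798 CPM. Aacs and Lpin1 are also on the list of fatty acid and triglyceride synthesis. Of 45 genes of fatty acid oxidation and PPAR-alpha targets, 0 were higher and 7 lower, with a median of -0.45. The acyl-CoA thioesterases Acot1 (-2.62) and Acot2 (-2.21), the peroxisomal enzyme Ehhadh (-2.24) and the hormone Fgf21 (-2.23) were among the 7. In bile acid synthesis and transport, 4 of 31 genes were higher and 3 lower (median -0.17), with Akr1d1 at 2.38, Abcb1a at 2.23, Slco1a4 at 1.65 and Cyp7b1 at -2.06. Apolipoproteins and lipoprotein handling had a median of -0.08, with 2 of 22 members higher, the lipid transfer protein Pltp (1.93) and the lipase Lpl (1.17).

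The insulin signalling list had a median log2 ratio of 0.05 over 36 genes, inside the central 95% of matched random lists, with 1 gene higher and 0 lower. That gene was the lipid phosphatase Inpp5d (1.20, 13 and 50 counts), chosen after its values were seen. The insulin receptor Insr stood at 0.14 (interval 0.07 to 0.21), Irs1 at -0.27 (-0.43 to -0.12) and Irs2 at 0.10 (-0.08 to 0.30). Igf1 had 0.40 and Igfbp2 -0.83. The gluconeogenic enzymes Pck1 and G6pc each had a log2 ratio of 0.08. In the list of gluconeogenesis, glycolysis and glycogen, 7 of 38 genes were higher and 1 lower (median 0.35). Pyruvate kinase Pklr (2.13), the transcription factor Onecut1 (2.31) and the coactivator Ppargc1a (1.73) were higher, and Ppp1r3c, which targets a phosphatase to glycogen, had -1.92.

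Genes of the endoplasmic reticulum and of stress pathways went in both directions. Of 30 ER chaperones and ER-associated degradation genes, 0 were higher and 6 lower (median -0.38), among them Derl3 (-2.59), Sdf2l1 (-1.87), Creld2 (-1.56) and Pdia4 (-1.30). The chaperone Hspa5 had 0.75, Xbp1 -0.25, Ddit3 0.70 and Atf3 -0.16. Integrated stress response targets had 3 of 20 members higher and 2 lower, with Ddit4 at 1.80, Vldlr at 1.07 and Gdf15 at -1.24. Among metallothioneins and zinc transporters, 2 of 21 were higher and 1 lower: the zinc-binding proteins Mt2 (1.89, interval 1.73 to 2.19) and Mt1 (1.26, interval 1.11 to 1.49) were higher, and Slc30a10 had -1.80. The zinc exporter Slc30a1 had -0.03 (-0.18 to 0.11). Mt2 shares its place on chromosome 8 with the opposite-strand model RP23-98C9.5, whose counts were nearly equal (195 against 197 in the control), so the value of either is uncertain. NRF2 targets (median 0.06, 2 of 23 higher and 3 lower) and antioxidant enzymes (0.05, 1 of 21 higher, Gpx3 at 1.33, chosen after its values were seen) lay inside the central 95% of random lists. Gstm3 had 2.30, Abcc4 1.22, Osgin1 -1.13, Aox1 -1.05, catalase Cat -0.36 and Sod1 -0.03. Hmox1 had 5 counts in the control and 14 at 8 weeks, Nqo1 had 1 in each, and no change in Nqo1 was detectable at this depth.

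Markers of Kupffer cells and macrophages, the resident phagocytes of liver, were higher for 16 of 18 genes with a median of 1.81. Cd5l had a log2 ratio of 2.41, Mpeg1 2.26, Timd4 2.11 and Cd163 2.06. Beside these, 16 of 38 interferon-stimulated genes were higher and 0 lower (median 0.83), including Ifi44 (2.55), Irf7 (1.87), Ifit2 (1.82) and Oas2 (1.76). In the NF-kappaB list 6 of 30 genes were higher (median 0.23), including Vcam1 (1.70), Cxcl1 (1.56), Tlr4 (1.24) and Il18 (1.18). The acute phase list holds proteins secreted by hepatocytes in inflammation and some that are not secreted, such as Socs3 and Stat3. It had 10 of 36 members higher and 1 lower (median 0.26), with Orm2 at 3.85, Saa1 at 3.76, Saa2 at 3.53 and Lcn2 at 2.65. Without Mt1 and Mt2, left out after the values were seen, 8 of 34 were higher (median 0.16). The lower member, chosen after its values were seen, was Hamp, the iron hormone hepcidin (-1.68). Saa genes are near-identical, and their single values are uncertain. Socs3 had -0.53, and Tnf and Il6 had 0 and 1 counts at 8 weeks. Liver endothelial markers had a median of 0.38, stellate cell and fibroblast markers 0.27, erythroid markers 0.53, monocyte and neutrophil markers 0.44, lymphocyte markers 0.12 and hepatocyte markers 0.06.

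Skeletal muscle markers were found in the 8-week library almost alone. All 10 were called higher, with a median log2 ratio of 3.73, or 5.03 with the 6 genes at 0 counts in the control at their bound. Together they had 26 counts in the control, 2743 at 8 weeks and 16 at 12 weeks. The myosin Myh1 went from 2 to 791 counts, troponin Tnnt3 from 3 to 729, and Myh2, with 0 counts in the control, was at least 111-fold higher. Ube2c, a cell cycle gene, had 198 counts at 8 weeks, the number that the muscle gene Tnnc2 had there, and their positions on chromosome 2 overlap. Core clock genes also differed: 8 of 21 were higher and 4 lower. Arntl, which drives the clock's positive limb, had -2.99, while Usp2 (2.33), Ciart (2.19) and Wee1 (1.92) were higher.

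The second comparison asked how the liver after 12 weeks of ZnO nanoparticles differed from the same control. At 2-fold, 15 of 18 macrophage markers, 11 of 21 female-biased liver genes, 16 of 36 acute phase proteins and 9 of 36 lipogenic genes were higher, and 4 lipogenic genes were lower. Saa2, a serum amyloid of the acute phase, went from 3.32 to 684 CPM (7.31), and Lcn2, an iron-sequestering lipocalin, from 1.55 to 114 CPM (5.50). Mt2 went from 14.5 to 398 CPM (4.68, interval 4.57 to 4.99) and Mt1 from 23.9 to 305 CPM (3.62, interval 3.51 to 3.84). The zinc exporter Slc30a1 stood at 0.10 (-0.05 to 0.25). In all, 454 genes were higher and 196 lower, of which 382 and 155 were protein-coding.

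Acute phase proteins had 16 of 36 members higher and 0 lower, with a median of 0.94. Saa1 had 5.99 and Orm2 4.52. The NF-kappaB list had 10 of 30 members higher and 0 lower (median 0.72), including the chemokines Cxcl1 (4.44) and Cxcl9 (1.96) and the interleukin antagonist Il1rn (1.96). Socs3, a feedback inhibitor of cytokine signalling, had 1.00 (interval 0.76 to 1.41), while Tnf had 3 counts and Il6 had 2. Kupffer cell markers had 15 of 18 members higher (median 1.45), with Mpeg1 at 2.03, Cd5l at 1.74, Cd163 at 1.69 and C1qb at 1.66. Of 18 monocyte and neutrophil markers only 7 were kept, with 2 higher (median 0.84). These were Itgam (1.27) and Lcn2, which is also on the acute phase list. Interferon-stimulated genes had 5 of 38 higher and 0 lower (median 0.60), with Gbp7 at 1.51, Gbp2 at 1.49 and Gbp3 at 1.45. Endothelial markers had a median of 0.28, stellate cell and fibroblast markers 0.37 and hepatocyte markers 0.07. Lymphocyte markers had -0.16, with Ptprc at 1.28 and Cd74 at 0.58.

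Female-biased liver genes had 11 of 21 members higher and 0 lower (median 1.20), with Cyp2a4 at 6.51, Cyp2b9 at 5.98 and Cyp2b13 at 4.08. Male-biased genes had 5 of 23 members lower and 1 higher (Keg1, 1.08, chosen after its values were seen), with a median of -0.33. Elovl3 had -4.31, Selenbp2 -2.78, Cspg5 -2.56 and Cyp4a12b -2.32, whereas Mup20 stood at -0.11 and Mup21 at -0.33, both given for comparison with 8 weeks after their values were seen. Ddx3y had 0.05, Eif2s3y -0.37 and Xist 13 counts. Cytochromes P450 had 13 of 41 members higher and 1 lower (median 0.18), with Cyp2c70 at 2.92 and Cyp2d40 at -2.50.

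In lipid metabolism, 9 of 36 genes of fatty acid and triglyceride synthesis were higher and 4 lower (median 0.14), with Scd1 at 3.75, Thrsp at 3.64 and Elovl6 at 3.10, beside 3 higher and 1 lower of 21 clock genes. Cholesterol synthesis and uptake had a median of 0.10, inside the central 95% of random lists, with Lpin1 (1.52) and Aacs (1.52) higher and Hmgcs1 (-1.12) lower. Lpin1 and Aacs, its only 2 members called higher, are also on the list of fatty acid and triglyceride synthesis. Fatty acid oxidation and PPAR-alpha targets had 7 of 45 members lower and 2 higher (median -0.50), with Cyp4a10 at -2.56, Ehhadh at -2.35, Cyp4a31 at -2.26 and Acot1 at -1.45. Bile acid synthesis and transport had 3 of 31 higher and 4 lower (median -0.19). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had -1.47 and Cyp8b1 -2.04, while Abcb1a had 2.28 and Cyp39a1 1.93. Among lipoprotein genes Pltp had 1.29, Lpl 1.17 and Angptl8 -1.16 (list median -0.17). The Cyp4a, Cyp2 and Acot genes belong to families of similar sequence, and single values are uncertain.

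The insulin signalling list had a median of 0.04 at 12 weeks, inside the central 95% of random lists, and Socs3 was its 1 member called higher. Insr stood at 0.05 (-0.02 to 0.12), Irs1 at -0.51 (-0.69 to -0.36) and Irs2 at 0.46 (0.29 to 0.66). Igf1 had 0.62 and Igfbp2 -0.82. Pck1 had -0.35 and G6pc -0.72, neither of them 2-fold. In the glucose and glycogen list, 5 of 38 genes were higher and 1 lower (median 0.22), with Onecut1 at 2.40, Ppp1r3g at 2.22 and Ppp1r3c at -2.16, and Pklr went from 49.4 to 142 CPM. ER chaperones had 0 members called in either direction (median -0.07), with Hspa5 at 0.79, Xbp1 at 0.64 and Hsp90b1 at -0.50. Among integrated stress response targets Chac1 (1.83) and Ddit4 (1.16) were higher, and Gdf15 (-1.35), Trib3 (-1.17) and Fgf21 (-1.11, chosen after its values were seen) were lower. Ddit3 had 0.74 and Atf3 0.27. NRF2 targets had a median of -0.11 and antioxidant enzymes -0.14. Hmox1 had 15 counts and Nqo1 had 2.

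Clock genes were called in fewer cases at 12 weeks, 3 higher and 1 lower of 21, with Arntl at -1.60, Usp2 at 1.30, Wee1 at 1.18 and Per2 at 1.13. Immediate early genes had 1 of 25 members higher and 4 lower (median 0.17), with Egr1 at -2.33, Cyr61 at -1.13, Gadd45b at -1.07 and Gadd45g at 1.55. All 31 proteasome subunits had negative log2 ratios at both times, with medians of -0.48 and -0.58 and 0 members called. Of 53 cytosolic ribosomal proteins, 51 were negative at 12 weeks (median -0.27), against a median of -0.04 at 8 weeks.

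**Figure D1:**
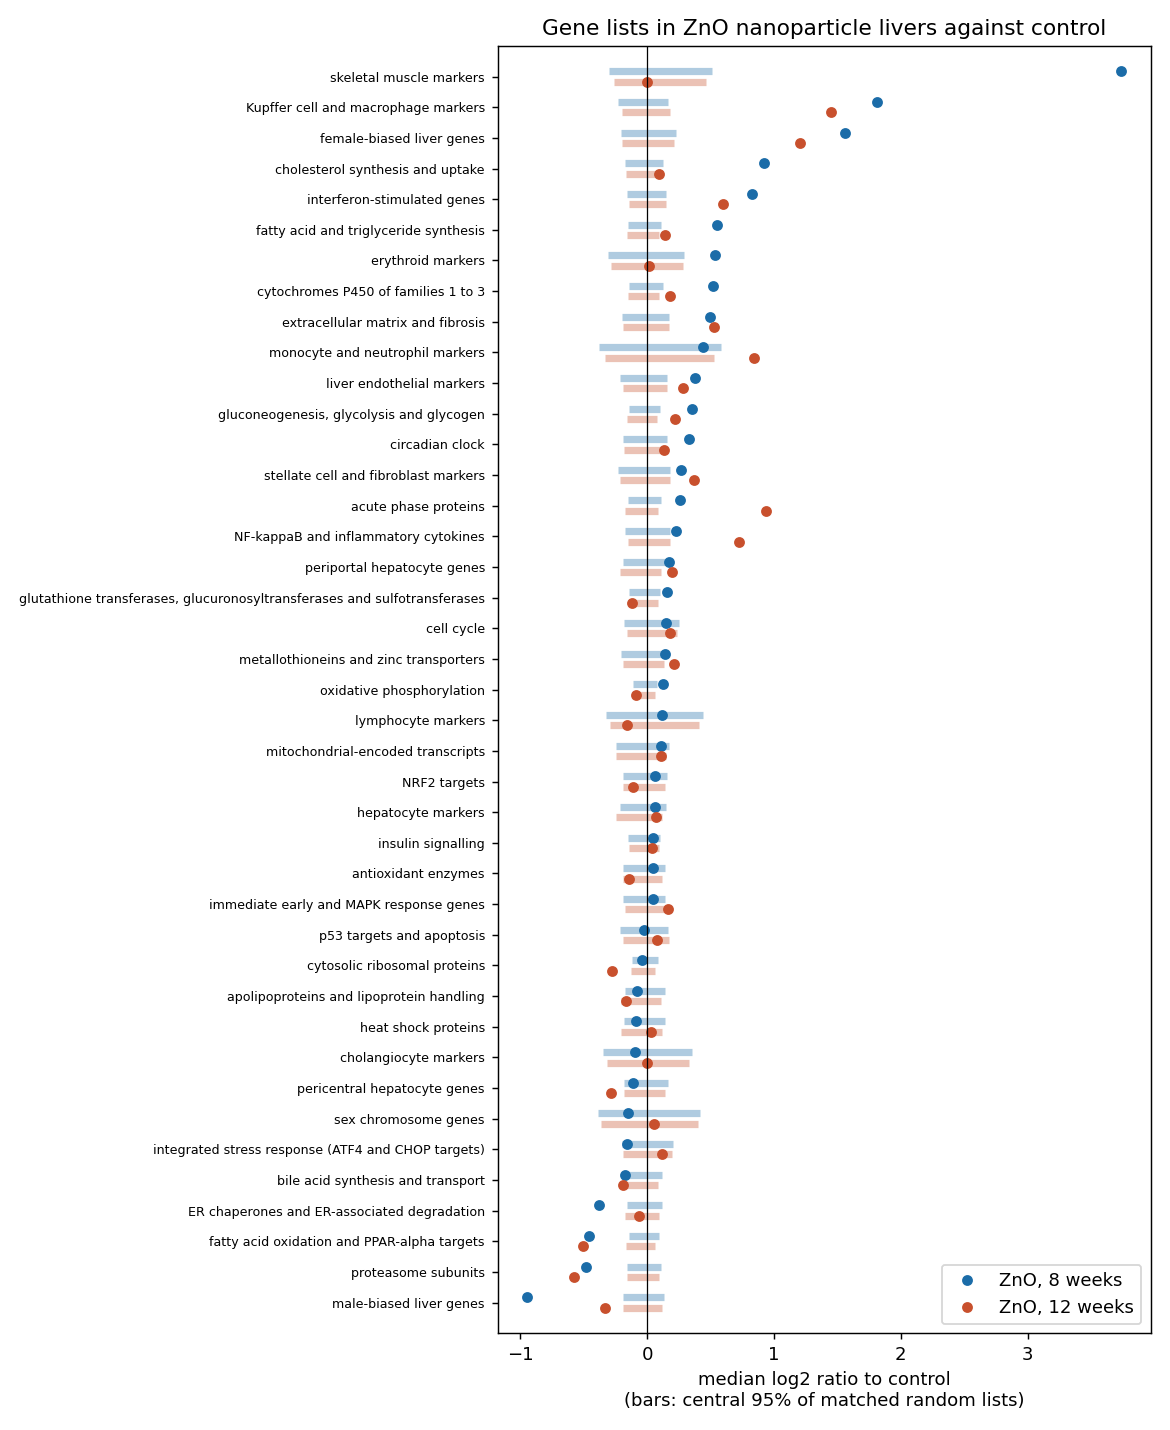
Median log2 ratio to the control over the genes of each of 41 lists, at 8 weeks (blue points) and 12 weeks (orange points), with 1 library per group. Bars span the central 95% of 10000 random lists matched on expression; the point of acute phase proteins lies at 0.26 at 8 weeks and 0.94 at 12 weeks, and that of skeletal muscle markers at 3.73 (5.03 with genes at 0 counts at their bound) and 0.00; with other scalings the sign flips for p53 targets at 8 weeks and cholangiocyte markers at 12 weeks.

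**Figure D2:**
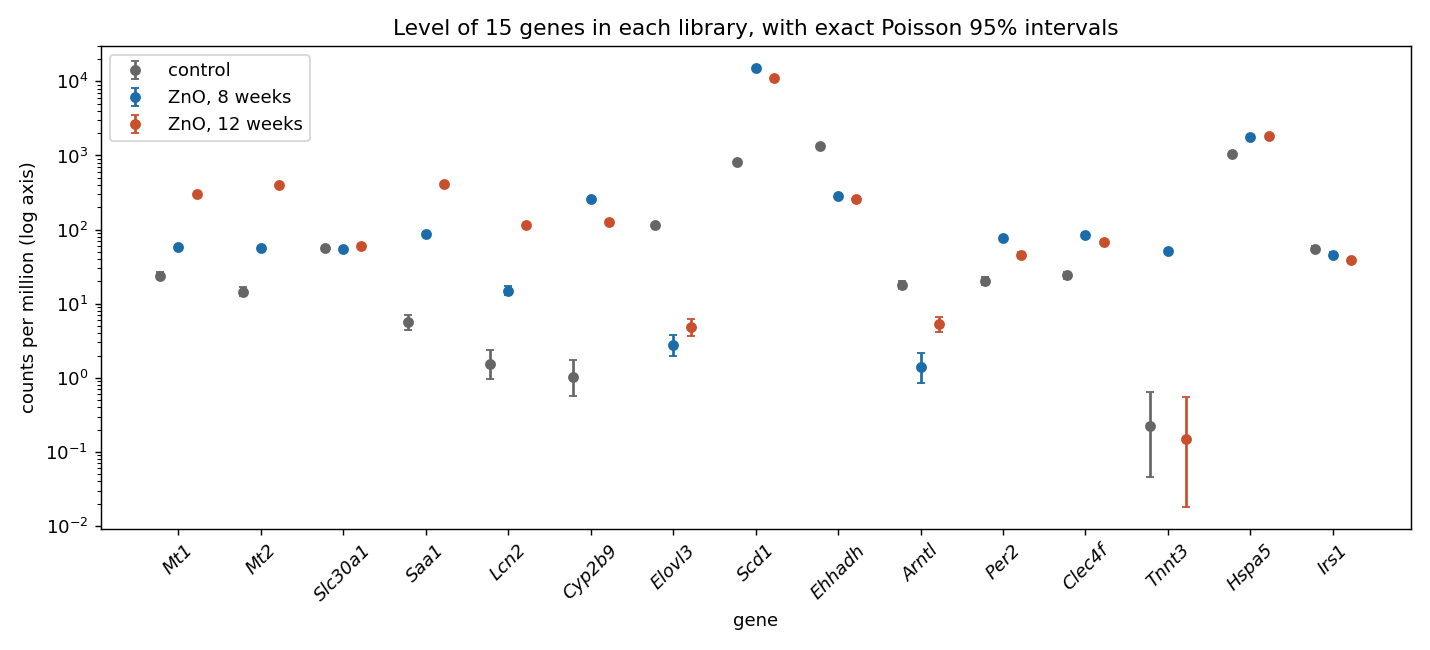
Level of 15 genes in CPM on a log axis in the control (grey), 8-week (blue) and 12-week (orange) library, with exact Poisson 95% intervals for counting error. Mt2 reads 14.5, 56.5 and 398 CPM in that order, and Slc30a1 reads 56.0, 54.6 and 60.0 CPM.

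The third comparison set the 12-week library against the 8-week library. At 2-fold, 10 of 36 acute phase proteins, 6 of 23 male-biased genes, 4 of 30 ER chaperones and 3 of 21 metallothioneins and zinc transporters were higher at 12 weeks, and 1 male-biased gene was lower. Of 27 cholesterol synthesis and uptake genes, 11 were lower. The 10 skeletal muscle markers, found in the 8-week library almost alone, were lower as well. Saa2 had a log2 ratio of 3.78, Lcn2 2.86, Mt2 2.79, Steap4 2.41 and Mt1 2.35. The pheromone carriers Mup21 (4.01) and Mup20 (2.96) and the glutathione transferase Gstp3 (3.84) had 12-week values of -0.33, -0.11 and 0.37 against the control. In all, 186 genes were higher and 180 lower; 143 were lower without the genes found in the 8-week library alone.

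All 27 genes of cholesterol synthesis and uptake had negative log2 ratios between 12 and 8 weeks, 11 of them called lower (median -0.71). Msmo1 had -2.04, Idi1 -1.73, Hmgcs1 -1.46 and Fdps -1.38. ER chaperones had 4 of 30 members higher and 0 lower (median 0.47), with Derl3 at 2.35, Sdf2l1 at 1.58, Creld2 at 1.26 and Hyou1 at 1.03. Acute phase proteins had 10 of 36 members higher and 0 lower (median 0.69), and male-biased genes 6 of 23 higher and 1 lower (median 0.45), including Mup7 (1.80) and Cyp7b1 (1.74). In fatty acid and triglyceride synthesis, Pparg (-1.75), Srebf1 (-1.08) and Thrsp (-1.07) were lower and the lipid droplet protein Plin2 was higher (204 CPM at 8 weeks and 579 at 12). Among fatty acid oxidation genes Acot2 had 1.99 and Pdk4 1.94. Cyp7a1 had -2.07. Skeletal muscle markers had a median of -3.58, or -4.52 with 5 genes at their bound, and 17 of 18 Kupffer cell markers were negative without any call (median -0.35). The median of insulin signalling was 0.00, and its sign changed with the scaling of the libraries.

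The changes at 8 and 12 weeks were then set side by side across genes, which are not independent replicates. In both comparisons, 266 genes were higher and 121 were lower, and 2 genes were called in opposite directions. For 3 simulated unchanged libraries sharing 1 control, with noise taken from the difference between the treated libraries, a mean of 340 and 339 genes were called, against 912 and 650 observed. The simulated mean counts in both were 29.6 and 31.8 (highest 40 and 45), and independent lists of the same sizes would share 18.8 and 4.13. The correlation across genes was 0.697, against 0.499 simulated, and the covariance was 0.204 against 0.0891, a difference of 0.115. With 1 control library the control could not be split. The simulation gave the control the same noise as the treated libraries, so it cannot cover a control that deviates more. Part or all of the excess may therefore come from the control.

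**Figure D3:**
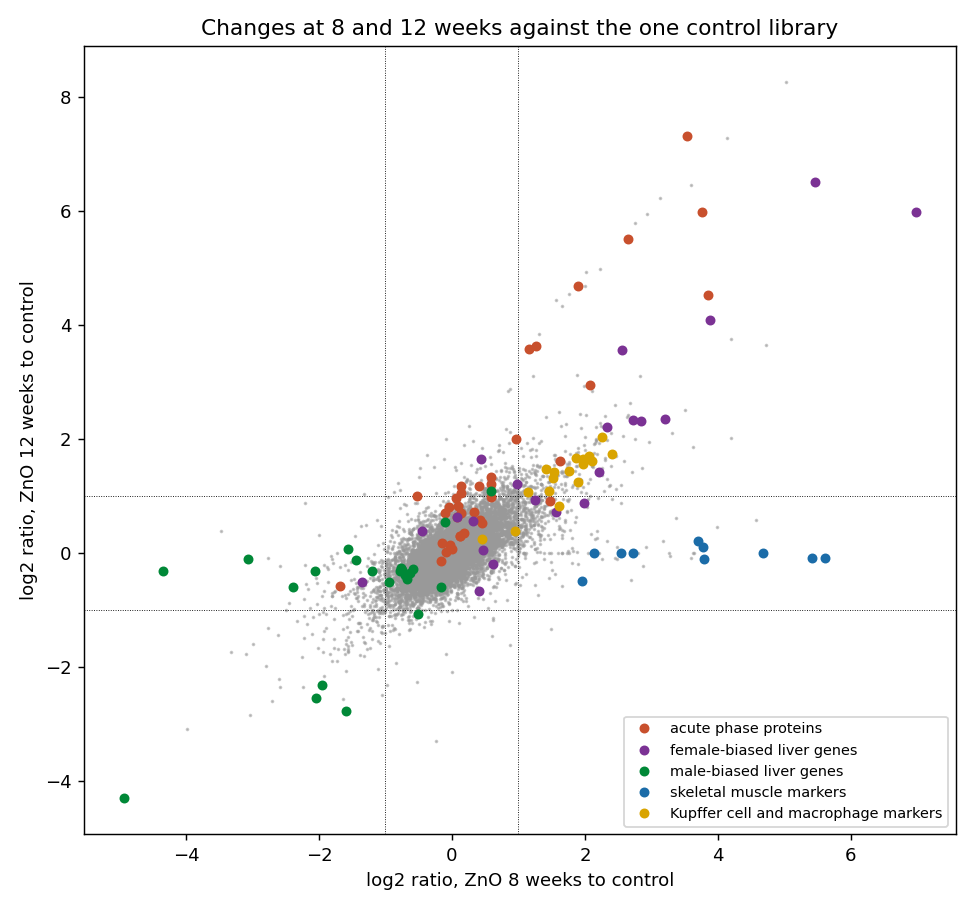
Log2 ratio to the control at 8 weeks (horizontal axis) and 12 weeks (vertical axis) for 14585 genes (grey), with 5 lists in colour and dotted lines at 2-fold. Skeletal muscle markers lie along the horizontal axis, and acute phase proteins reach 7.31 at 12 weeks (Saa2).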

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

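All tests of explanations in this part were chosen after the results were seen. The genes below went in opposite directions against the control at 8 and 12 weeks, and the difference was not tested, since each time has 1 library. By the log2 ratio of 12 to 8 weeks, with the ratios to the control at 8 and 12 weeks in brackets, Col20a1 had 2.36 (-1.32 and 1.04), Pdk4 1.94 (-0.96 and 0.98), Pparg -1.75 (0.61 and -1.14), Msmo1 -2.04 (1.30 and -0.74) and Cyp7a1 -2.07 (0.60 and -1.47). Obp2a had 3.08, from 49, 0 and 99 counts in the control, 8-week and 12-week libraries, and was at least 35.7-fold higher at 12 than at 8 weeks. H19 had -2.83, from 26, 103 and 2 counts, with a counting interval of -8.64 to -3.68 without the added CPM. Col20a1 and H19 were the only 2 genes called at 2-fold both times in opposite directions, and both were named after their values were seen.

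The first pattern is the clock genes: in the 8-week library the median of 11 genes in opposite phase to Arntl (Per1 to Per3, Nr1d1, Nr1d2, Dbp, Tef, Hlf, Ciart, Usp2 and Wee1) exceeded that of Arntl, Clock, Npas2 and Nfil3 by 2.53 on the log2 scale, and by 1.62 at 12 weeks, although Nr1d1 itself had -0.80 and -0.26. The phase of each gene was assigned from textbook knowledge after the values were seen. Collection of the livers at another hour or in another feeding state may account for this, since it predicts such opposite movement. An effect of the particles on the clock predicts the same and stays open, untested. Feeding state and hour also change lipogenic, cholesterol synthesis and PPAR-alpha target genes in liver, so the values of those lists carry the same doubt, which was not tested.

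The second pattern is the sex-biased genes. RNA of female animals in the treated samples is argued against by the Y-linked genes, whose median was -0.12 at 8 weeks and 0.05 at 12 weeks, and by Xist, with 14, 9 and 13 counts in the 3 libraries. Reads shared within gene families are argued against as the whole cause for the female-biased genes, whose 8 members outside such families had a median of 2.104 at 8 weeks, and for the Mup genes, whose 48 genes and pseudogenes in sum had a log2 ratio of -1.13 then, since sharing within a family leaves its sum. For the other male-biased genes, the 7 members outside families had a median of -0.58, at the 0.075 percentile of random lists with 6 of 7 negative, but it narrowly missed the bound set and the members ranged from -4.93 to 0.59, so that explanation cannot be told apart from a change of the genes. An effect of the treatment and differences between individual animals stay open as well, untested with 1 library per group. The hour of collection and feeding state, raised above for the clock genes, were not tested for this pattern and stay open too.

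The third pattern is Mt1 and Mt2 at 12 weeks. Reads shared with the model overlapping Mt2 are argued against as the whole cause by Mt1, which lies outside that model and had a log2 ratio of 3.62. Zinc acting through the metal-responsive factor MTF1 as the whole cause is argued against in this library by Slc30a1, a target of the same factor fixed in advance, at 0.10 with a counting interval up to 0.25, though 1 gene was read and the spread between animals is unknown. An acute phase response, which also induces metallothioneins, may contribute: without Mt1 and Mt2 that list had a median of 0.87 at 12 weeks and 0.16 at 8 weeks. A partial effect of zinc stays open.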

How the results depend on the processing

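No paired analysis was possible because each group has 1 library and no result comes from a test. Counts of called genes are given as higher and lower for 8 weeks against control, 12 weeks against control, and 12 against 8 weeks, beside 605 and 307, 454 and 196, and 186 and 180. With a pseudocount of 0.1 CPM they were 1059 and 597, 943 and 415, and 443 and 405. With 5 CPM they were 269 and 160, 179 and 80, and 89 and 72. A pseudocount of 0.5 gave 309 higher between the treated libraries. At 1.5-fold they were 1547 and 1162, 1354 and 907, and 789 and 690, and at 3-fold 225 and 92, 132 and 48, and 61 and 67. Requiring 1 CPM in both libraries, chosen after seeing the data, left 394 higher at 8 weeks and 105 lower at 12 against 8 weeks. With 5 CPM added, 114 genes were higher and 59 lower at both times, and the excess covariance was 0.0608. These shifts follow from the settings' own construction, as a larger added value shrinks the ratios of low genes.

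The other 62 of 92 values of counts and overlap under alternatives stayed within 1.5 times. The scalings moved the median of all genes by at most 0.03. Of 849 list medians under alternatives, 787 moved by less than the spread of random lists, and no list outside the central 95% changed sign. For named genes, 2096 of 2376 values stayed inside their counting interval, taken with 1 CPM added. That no called gene changed sign was fixed by the settings. An added value keeps the order of 2 libraries, and the scalings moved ratios too little to reverse a 2-fold change. Near 0, the sign changed with scaling for insulin signalling and apolipoproteins between the treated libraries, p53 targets at 8 weeks and cholangiocyte markers at 12 weeks. Requiring an interval that excludes equality and leaving out genes found in the 8-week library alone, both chosen after seeing the data, moved no count by over 1.5 times. Neither could do so, although their values are among the 92. A 2-fold ratio with 1 CPM added already needs a count difference whose interval excludes equality. The other setting left out only 39 genes, too few for such a move. Depth limits genes such as Nqo1, Tnf and Il6, at 3 counts or fewer. Dropping the filter and using the most abundant entry per symbol could not change a count by construction and are not among these values. Intervals from the files were not run as an alternative, since the files list none.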

Other observations

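Tubulins, the subunits of microtubules, were picked as a family chosen after its values were seen. All 9 kept alpha and beta tubulins had negative log2 ratios at both times, with 4 called lower at 8 weeks and 6 at 12 weeks. Tubb2a had -2.59 at 8 weeks and -2.35 at 12 weeks, Tubb4b -1.56 and -1.73, and Tuba4a -1.33 and -1.57. Of 21 heat shock genes, 2 were higher and 1 lower at 8 weeks, and 3 were higher and 0 lower at 12 weeks: the inducible chaperones Hspa1a (8.62, 49.4 and 40.2 CPM in the control, 8-week and 12-week libraries) and Hspa1b (log2 ratios of 2.33 and 1.98) were higher at both times, the co-chaperone Bag3 had 0.92 and 1.07, Hspb1 had -1.23 and -0.45, and the list median was -0.09 and 0.03. The cell cycle inhibitor Cdkn1a had -2.76 and -1.33, with medians of the p53 list of -0.02 and 0.08. Mki67, a proliferation marker, had 1.63 at both times, and the cell cycle list had 0.15 and 0.18.

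Extracellular matrix genes had medians of 0.50 and 0.52, with 20 of 22 members positive at each time and 1 call, Col3a1 at 8 weeks (1.01, chosen after its values were seen). Periportal hepatocyte genes had 0.17 and 0.20, with Hsd17b6 at 1.76 and 1.41 and Aldh1b1 at 1.32 and 1.52. Pericentral genes had -0.11 and -0.29, with Cyp2a5 at 2.57 and 2.06, and with Axin2 (-1.24) and Lgr5 (-1.23), targets of Wnt signalling, lower at 12 weeks. Oxidative phosphorylation had 0.13 and -0.09 over 57 genes with 0 calls, and mitochondrial-encoded transcripts 0.11 at each time. Phase II enzymes had 0.16 and -0.12, with 7 of 45 higher and 1 lower at 8 weeks. At 12 weeks 5 were higher, among them Gstm3 (2.30 and 1.66), and 0 lower, while 26 of the 45 were negative.

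Among lists with too few kept genes for a position, the adipocyte markers Cidec and Adrb3 had -1.45 and -2.17 at 8 weeks and -0.79 and -1.25 at 12 weeks, and Fabp4 had 0.70 and 0.74. The pancreatic markers Cela1 and Cela2a had -0.31 and -0.79 at 8 weeks and 0.07 and 0.02 at 12 weeks; Ctrb1 had 21, 1 and 2 counts and Pnlip 18, 1 and 0. The intestinal markers Fabp2 and Lgals4 had -0.16 and -0.10 at 8 weeks and -0.79 and 0.73 at 12 weeks, and of these genes Cela1 and Cela2a, Fabp4 at 8 weeks and Cidec at 12 weeks were chosen after their values were seen. Cholangiocyte markers had medians of -0.10 and 0.00, the last with a sign that changes with scaling, erythroid markers 0.02 at 12 weeks, and sex chromosome genes -0.15 and 0.05.

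The skeletal muscle markers, a list fixed in advance, were led at 8 weeks by Myh1 (791 counts), Tnnt3 (729) and Myh2 (351). Whether this RNA came from muscle tissue carried over with the liver was not tested, and the values of these genes are not read as changes in liver. Without the 39 genes found in the 8-week library alone, 566 genes were higher at 8 weeks against control and 143 lower at 12 against 8 weeks. Those 39 genes had 3 counts or fewer in each of the other libraries, so not every muscle gene is among them. The muscle gene Ttn, with 1, 353 and 8 counts in the control, 8-week and 12-week libraries, is still in both numbers.

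A group of 11 predicted gene models, also chosen after their values were seen, had 79 counts in the control, 3507 at 8 weeks and 30094 at 12 weeks. They lie at 3 places, on chromosomes 2, 9 and 14 of mm10. Gm10800 on chromosome 2 (98666547 to 98667301) had 55, 2335 and 20558 counts, and Gm26870 on chromosome 9 (3000282 to 3038313) had 8, 386 and 3259. For comparison, 1739 olfactory and vomeronasal receptor genes, which liver is not known to use, together had 397, 416 and 453 counts. All 11 models were at least 2-fold higher than the control at both times. All except Gm26870 are annotated as protein-coding, so they are among the 505 and 382 protein-coding genes higher at 8 and 12 weeks. Counts of the models rose in like proportion, as for Gm11168 with 4, 128 and 1046. Whether they are separate signals was not tested, and no explanation was tested for this group.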
